A study of Mus musculus with 6 samples.

How the data were processed

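Cancer cells of an adult mouse glioblastoma model had been sorted for the red fluorescent protein tdTomato from the cortex, the corpus callosum and the tumour centre. One library per region was made in each of 2 batches with the 10x Genomics 3' NEXT GEM v3.1 kit, which gave 6 libraries and 2 per region. The labels do not state which animals the cells came from, so the p-values measure the spread between these libraries. The deposited values are counts, namely unnormalised UMI counts per gene and cell for 31055 features. The features include the transgenes EGFRvIII, a constitutively active form of the epidermal growth factor receptor, and tdTomato. The submitters' processing notes name Cell Ranger 3.0.2, Seurat 3.1.4 and the builds mm10 and GRCm38 without saying which step each was used for. The annotation release and the rule by which barcodes were called cells are not stated.

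Cells were kept with at least 500 detected genes and at most 20% mitochondrial UMIs. Doublets were scored per library with the method of Scrublet in scanpy 1.11.5. Its automatic threshold called very few cells, so the highest scores were removed instead, at 0.8% per 1000 cells that passed the filter, which took out 89 cells. Of these, 42 came from each tumour centre library. Fewer cells were removed than the automatic threshold had called in both corpus callosum libraries (0 against 4 and 2 against 3) and in cortex of batch 1 (2 against 3). After counts were scaled and logged, 2200 variable genes, scaled within each batch, gave 30 principal components, a graph of 15 neighbours and 25 Leiden clusters at resolution 1 (leidenalg 0.10.2). Clusters took the class name whose markers scored highest, relative to their level in the cluster richest in each. At least 3 of its markers had to be found in 10% of the cells and the score had to reach 0.25. No other class could have more markers among the cluster's 10 leading genes, and a cluster far shallower than its libraries needed 1 marker among them. This naming rule replaced a first version after the clusters had been seen and before any gene was tested. It left 2 clusters unnamed, both because another class had more markers among the leading genes, and gave 5 classes, whose names describe marker genes and not origin. The neural-lineage cells were all cells outside the immune-like and vascular-like clusters, 5071 of 5917.

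Counts were summed over the neural-lineage cells of each library, and separately over its oligodendrocyte precursor-like cells, the most abundant class. Genes were filtered with filterByExpr and tested with the edgeR 4.0.16 quasi-likelihood F test (R 4.3.3, TMM scaling, two-sided, all 6 libraries in each fit), with region as the only term. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the genes of a comparison. Standard errors of log2 fold changes are the fold change divided by the root of F. Levels are CPM, counts scaled to a common library size with the TMM factors, as mean ± SD of 2 libraries. The labels assign both batches to every region, and differences between batches correlated across genes between regions (Pearson r 0.637 for tumour centre with cortex, 0.588 for tumour centre with corpus callosum and 0.509 for cortex with corpus callosum, over 13311 genes that are not independent replicates). The first principal component, with 54.4% of the variance, parted the batches. A fit with batch as a second term was therefore run as an alternative, and its counts stand beside the others.

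The 36 gene lists, the classes, the tests and the rule for naming genes were fixed before the data were examined. Of the lists, 33 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation and fry (limma 3.58.1) were alternatives. The rule named genes past the threshold with a mean of at least 20 CPM and the same sign in both batches, up to 8 in each direction, and 3 members of each list that passed. With under 5 calls it named the 10 genes with the smallest p, which are said not to pass. Since no gene passed by region alone, the same rule was also applied to the fit with batch as a term, a choice made after the counts were known. It named 53 genes for cortex against tumour centre, 42 for corpus callosum against tumour centre and 47 for corpus callosum against cortex, of which 2, 1 and 0 are predicted genes and are not described. Another 3 named genes are not reported here.

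Shares of cells carry exact 95% Clopper-Pearson intervals, which cover counting error only. Means of shares were compared with exact permutation tests (two-sided), which ignore batch and cannot go below p = 0.333 with 2 libraries against 2. The share of cells with a UMI of Mki67 or Top2a was taken after each cell had been thinned to 2000 UMIs, with shallower cells left out. Where both libraries of a group held no UMI of a gene, folds were computed against 3 counts per library.

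On simulated counts with the spread of these libraries, 100 genes were changed by 2-fold and 100 by 4-fold, some raised and some lowered. The fit by region alone recovered 0% of either group and made 0 false calls. The fit with batch as a term recovered 89%, 93% and 82% of the genes changed by 2-fold in the order of comparisons above and 100% at 4-fold. It also made 30, 68 and 28 false calls among 13144, 13173 and 13178 genes tested. These were a larger share of its calls than the threshold allows, so single genes called by that fit are uncertain. Those false calls arose beside the many changed genes of the simulation, so their number is not one to expect in the real libraries. Camera gave the changed lists adjusted p of at most 1.1e-34 and the unchanged lists at least 0.0955. Genes were drawn independently in the simulation, so it cannot show how camera behaves on lists whose genes vary together.

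The alternatives tried were DESeq2 1.42.0, RLE size factors in edgeR, no filter on low counts, a minimum log2 fold change of 1, batch as a term, no quality filter, a stricter one (1000 genes, 10% mitochondrial UMIs), doublets kept, resolution 2, genes not scaled within batch, all cells, no mature oligodendrocyte-like cells, libraries thinned to one total, 4000 or no thinned UMIs per cell, and leaving out each library. Chosen after seeing the data were cells with a UMI of EGFRvIII, cells with a UMI of Xist and none of 4 Y-linked genes, and cells of at least 5000 UMIs. So were the removal of the cluster richest in interferon-induced RNA, the removal of genes sharing sequence, and the fits that join batch as a term with another choice. For shared sequence, the last 500 bases of each annotated transcript were cut into windows of 60 bases, and the share of windows also found in another gene was taken for genes with at least 30 UMIs. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9. Clustering by trajectory, copy number inference and ligand analyses were not done.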

Results

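The series title and design ask how glioblastoma cells differ between regions of the brain. Single-cell RNA was measured in tdTomato-sorted cancer cells from 3 regions in 2 batches, and libraries are named here by region (Cx for cortex, CC for corpus callosum, Co for tumour centre) and batch number. The deposited counts hold 7386 barcodes, of which 6006 passed the quality filter and 5917 were used. Total UMIs were 5563611 in Cx1, 1583792 in CC1 and 29790697 in Co1, and 5627997 in Cx2, 8891683 in CC2 and 47974047 in Co2. Neural-lineage cells numbered 295 in Cx1, 117 in CC1, 1717 in Co1, 287 in Cx2, 426 in CC2 and 2229 in Co2. Their median depth was 2450, 2504 and 13275 UMIs per cell in Cx1, CC1 and Co1, and 11856, 17717 and 17926 in Cx2, CC2 and Co2. CC1 stood apart, since only 41.6% of its barcodes passed the filter, against 74.3% to 86.2% in the other libraries.

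Most sorted cells resembled oligodendrocyte precursors, with 4423 of the 5917 cells (74.7%) in clusters named by markers such as Pdgfra and Olig1. The other named classes were immune-like cells (820), mature oligodendrocyte-like cells (160), astrocyte-like cells (88) and vascular-like cells (26), and 400 cells fell in clusters that took no name. Mature oligodendrocyte-like cells, rich in myelin transcripts, were 8.46% ± 4.3 of neural-lineage cells in cortex, 8.12% ± 5.44 in corpus callosum and 1.3% ± 1.02 in tumour centre (SD, n = 2 each). Within each batch both peripheral shares exceeded that of the tumour centre, with 5.42% in Cx1, 4.27% in CC1 and 0.582% in Co1, and 11.5% in Cx2, 12% in CC2 and 2.02% in Co2. Astrocyte-like cells were 4.14% ± 1.54 of neural-lineage cells in cortex, 1.32% ± 0.54 in corpus callosum and 1.43% ± 0.38 in tumour centre. Immune-like cells followed batch more than region, at 42.9% of all cells in Cx1, 25.3% in CC1 and 23.2% in Co1 but 5.13%, 3.15% and 0.179% in Cx2, CC2 and Co2.

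The oligodendrocyte precursor-like share of neural-lineage cells was 81.9% ± 2.05 in cortex, 82.9% ± 9.68 in corpus callosum and 89.2% ± 0.41 in tumour centre (SD, n = 2 each). Cortex differed from tumour centre by -7.23 points (exact permutation p = 0.333, the smallest that 2 libraries against 2 can give), with -6.07 in batch 1 and -8.39 in batch 2. Corpus callosum differed from tumour centre by -6.27 points (exact permutation p = 1), with 0.29 in batch 1 and -12.8 in batch 2, and by -13.1 points without CC1 and 0.58 without CC2. Corpus callosum differed from cortex by 0.96 points (exact permutation p = 1), with 6.35 and -4.43 in the batches, and by -5.88 points without CC1, 2.41 without Cx1, 7.80 without CC2 and -0.49 without Cx2. With this clustering the difference between corpus callosum and either other region was smaller than the spread between replicates, but not with others. With genes not scaled within batch, corpus callosum had 69.8% and 70.9% against 83.7% and 86.8% in tumour centre. There a cluster of 387 cells led by Meox1, Stmn3 and Cdo1 took no name. In the main clustering a cluster led by these genes was named precursor-like and held 28.6% of the class in CC1 and 0% in CC2. Naming may thus account for part of the shift in batch 1. Under stricter quality control corpus callosum had 87.8% and 77.4% against 68.3% and 70.8% in cortex. There a cluster of 140 cells with leading genes Cldn5, Gbp4, Igtp and Tgtp2 was named vascular-like and left out. Yet 82.1% of its cells had a UMI of EGFRvIII. The neural-lineage sum of Cx2 fell from 5230867 to 2622546 UMIs, while its cells of at least 5000 UMIs summed to 4988814 without that filter. No result under stricter quality control thus separates the filter from the loss of this cluster. Exact 95% intervals reached from 82.8% to 94.6% in CC1, which had the fewest cells, and from 87.5% to 90.2% in Co2.

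**Figure D1:**
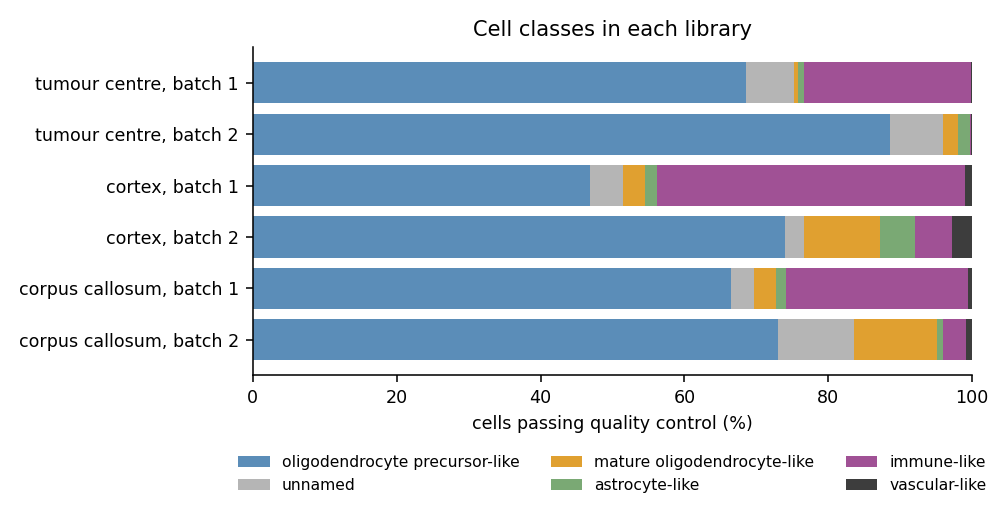
Share of each class among all cells that passed the quality filter, in percent, with 1 bar per library. Immune-like cells make up 42.9% of Cx1 and 0.179% of Co2, and mature oligodendrocyte-like cells are a larger share in cortex and corpus callosum than in tumour centre in both batches.

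Cells with a UMI of the division markers Mki67 or Top2a differed more between batches than between regions. After each cell had been thinned to 2000 UMIs, the shares were 14.2% ± 6.43 in cortex, 21.3% ± 4 in corpus callosum and 17.0% ± 8.09 in tumour centre (SD, n = 2 each). Batch 1 had 9.64% in Cx1, 18.5% in CC1 and 11.3% in Co1, and batch 2 had 18.7%, 24.1% and 22.8% in Cx2, CC2 and Co2. At this depth corpus callosum had the highest share in both batches, and each difference had 1 sign in both. The differences of -2.87 points (cortex minus tumour centre), 4.24 points (corpus callosum minus tumour centre) and 7.11 points (corpus callosum minus cortex) each had an exact permutation p of 0.667 in a test that ignores batch. In batch 1 and batch 2 they were -1.69 and -4.04, 7.13 and 1.35, and 8.82 and 5.39 points. Thinned to 4000 UMIs, the first was 3.29 points, with 17.1% in Cx1, 14.2% in Co1, 32.0% in Cx2 and 28.3% in Co2, and Cx2 exceeded CC2 (30.7%). Leaving out 1 library also sets unequal numbers of the batches against each other. The first turned to 1.68 points without Cx1 and 2.85 without Co2, the second to -1.48 without Co1, and the third moved to 2.57 without Cx1 and 11.7 without Cx2. Immune-like cells at the same depth had 5.26% in Cx1 and 4.49% in Co1. Without thinning the shares were 17.6% in Cx1, 17.1% in CC1, 20.7% in Co1, 35.9% in Cx2, 39.7% in CC2 and 43.2% in Co2. Cells under 2000 UMIs, left out of the thinned shares, numbered 129, 52, 172, 36, 57 and 314 in that order.

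The first comparison, cortex against tumour centre, asks how cells in the cortex differ from those in the tumour mass. Myelin genes were the group that rose most in cortex. All 22 measured members of the list of mature oligodendrocyte and myelin genes had positive log2 fold changes in both batches, with a median of 3.1. Mbp, which encodes myelin basic protein (ENSMUSG00000041607, chromosome 18, 82475146 to 82585637, GRCm38), averaged 1795 ± 121 CPM in cortex and 474 ± 66.9 CPM in tumour centre, a log2 fold change of 1.92 (SE 0.18). Mobp, another myelin protein gene, averaged 298 ± 87.6 against 26.0 ± 9.23 CPM, and Mag, a myelin adhesion protein gene, 404 ± 195 against 50.3 ± 12.5 CPM. Camera gave the list an adjusted p of 5.9e-46, and adjusted p = 0.498 with an estimated correlation. Counted when adjusted over the list alone, 18 of the 22 passed by region alone and all 22 with batch as a term, against 0 and 18 over all genes tested. The share of mature oligodendrocyte-like cells moved the same way, at 8.46% in cortex and 1.3% in tumour centre.

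Astrocyte genes also rose in cortex, with 18 of 22 measured members higher and a median log2 fold change of 0.79 (camera adjusted p = 4.2e-17, and p = 0.47 with an estimated correlation). Gja1, which encodes the gap junction protein connexin 43 (ENSMUSG00000050953, chromosome 10, 56377330 to 56402513), averaged 48.3 ± 24.6 CPM in cortex and 2.20 ± 0.24 in tumour centre, a log2 fold change of 4.44 (SE 0.49). Gjb6, which encodes connexin 30, averaged 16.9 ± 5.31 CPM in cortex and had no UMI in either tumour centre library, so that it was at least 124-fold higher. Mlc1, an astrocyte membrane protein gene, averaged 15 ± 3.2 against 3.60 ± 0.0022 CPM. By edgeR p-values adjusted over the list alone, 5 members passed by region alone and 13 with batch as a term, against 0 and 8 over all genes tested. Astrocyte-like cells moved with the list, at 4.14% of neural-lineage cells in cortex and 1.43% in tumour centre. Over cells with a UMI of EGFRvIII, the list's camera adjusted p was 0.328, or 0.059 with batch as a term. Astrocytes without the transgene are therefore not excluded as a source.

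Immune response genes rose in cortex as well. All 22 measured antigen presentation genes had positive log2 fold changes, with a median of 2.16 (camera adjusted p = 9.7e-13, and p = 0.675 with an estimated correlation), and 26 of 34 interferon response genes did, with a median of 1.04 (adjusted p = 1.0e-06, and p = 0.863 with an estimated correlation). Cxcl10, a chemokine induced by interferon, averaged 166 ± 76.8 CPM in cortex and 23.4 ± 10.1 in tumour centre. Nlrc5, which activates class I genes of the major histocompatibility complex, averaged 33.8 ± 28.7 against 5.45 ± 1.02 CPM, with log2 differences of 1.10 in batch 1 and 3.48 in batch 2. Zbp1 (log2 fold change 3.01), Stat2 (1.18), H2-Eb1 (4.04) and Ciita (2.81) were the other members with the smallest p. Adjusted over the list alone, 0 antigen presentation genes passed by region alone and 18 with batch as a term, and 1 interferon gene passed by region alone and 15 with batch as a term in this direction. Over all genes tested with batch as a term, these were 1 and 5. By region alone the interferon call was lost without Co1 and without Cx2, but with batch as a term it held without each library. It was also lost under stricter quality control (camera adjusted p = 0.0751), where a cluster with leading genes Gbp4, Igtp and Tgtp2 was left out as vascular-like. Without the cluster richest in interferon-induced RNA the call was lost too (camera adjusted p = 0.699, or 0.634 with batch as a term). RNA of immune cells is not excluded here, since microglia and macrophage genes rose too with batch as a term (adjusted p = 4.4e-04 and 0.0442) and immune-like cells were a larger share of Cx1 (42.9%) than of Co1 (23.2%) and of Cx2 (5.13%) than of Co2 (0.179%).

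Genes of cholesterol synthesis rose in cortex by a small and even amount, with all 24 members higher and a median log2 fold change of 0.32 (camera adjusted p = 8.2e-08, and p = 0.675 with an estimated correlation, 0.368 by camera over all cells). Fdps (0.83) and Idi1 (0.63) had the smallest p of the list, but 47.5% and 38.1% of the windows at their 3' ends occur in other genes, so their values are uncertain. Oligodendrocyte precursor genes fell, with 19 of 20 lower and a median log2 fold change of -0.40 (adjusted p = 1.7e-06, and p = 0.675 with an estimated correlation, 0.0592 by camera without Cx2). Vcan, a matrix proteoglycan gene, averaged 352 ± 20.1 CPM in cortex and 680 ± 225 in tumour centre, C1ql1 428 ± 4.61 against 710 ± 167 CPM, and Sox6, a transcription factor gene of the lineage, 205 ± 12.6 against 301 ± 45.9 CPM. Counted when adjusted over the list alone, 0 genes of either list passed by region alone, and 7 cholesterol and 12 precursor genes passed with batch as a term, against 1 and 2 over all genes tested.

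Other lists passed less firmly in cortex against tumour centre. Mature neuron genes rose (10 of 13 higher, adjusted p = 6.7e-04, and p = 0.675 with an estimated correlation), led by the synaptic kinase gene Camk2a at 12 ± 8.8 against 0.158 ± 0.159 CPM, followed by Slc17a7 (log2 fold change 4.31) and Nrgn (1.49). Committed oligodendrocyte genes rose (11 of 16, adjusted p = 0.0139, and p = 0.675 with an estimated correlation), led by Myrf, a transcription factor gene of myelination (50.3 ± 1.85 against 21.0 ± 2.27 CPM), Enpp6 (1.32) and Rras2 (0.82). Neural stem genes rose (10 of 16, adjusted p = 0.0249, and p = 0.675 with an estimated correlation), led by Thrsp (1.58), Hopx (1.43) and Egfr (1.92). Immediate early genes, which also respond to tissue dissociation, fell (22 of 27 lower, adjusted p = 0.0087, and p = 0.675 with an estimated correlation), led by Fosb (-2.73), Ier5 (-0.42) and Hsph1 (-0.46). Without Cx1 the neuron, committed and stem calls were lost (adjusted p = 0.392, 0.298 and 0.269). The stem call was also lost without Co1 (0.169), and the neuron and committed calls without Co2 (both 0.108). Other choices ended them too. The stem call was lost after thinning the libraries (0.684), over cells with EGFRvIII (0.178) and over all cells (0.368), the committed call over Xist-positive cells (0.701) and cells of at least 5000 UMIs (0.117), and the neuron call over all cells (0.233). Under stricter quality control the neuron, committed, stem and immediate early calls were lost (0.181, 0.0855, 0.0731 and 0.0731). That choice also left out a cluster named vascular-like although most of its cells had EGFRvIII. Over all cells the committed test pointed down (0.86) and the immediate early test up (0.669). With batch as a term, microglia (adjusted p = 4.4e-04) and macrophage genes (0.0442) also rose and genes of the G2 and M phases fell (0.0265), which had 0.124, 0.37 and 0.0892 by region alone, and none of these held with an estimated correlation. By edgeR p-values adjusted over the list alone, 1, 1, 0 and 0 members of these lists passed by region alone.

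Single genes did not pass for cortex against tumour centre when region was the only term. EdgeR called 0 of 13311 genes, with 609 at an unadjusted p under 0.05, and DESeq2 called 86 higher and 2 lower. With batch as a term edgeR called 255 higher and 33 lower. That fit made more false calls on simulated counts than its threshold allows, so single calls are uncertain. The total fell to 147 without Cx2 and reached 648 without CC1 and 1010 without Co1. It was 51 over Xist-positive cells, 64 over cells with EGFRvIII, 92 over cells of at least 5000 UMIs, 96 after thinning, 176 without shared-sequence genes and 191 without mature oligodendrocyte-like cells. Selenop, which encodes a secreted selenium transport protein (ENSMUSG00000064373, chromosome 15, 3268547 to 3280508), averaged 31.8 ± 8.03 against 3.29 ± 0.38 CPM (edgeR adjusted p = 0.29 by region, 0.0011 with batch as a term). The myelin genes Ermn, Opalin, Car2, Apod, Ppp1r14a and Mal had the largest log2 fold changes among those called with batch as a term (3.66 to 4.39 by region alone). Fam107a (5.65), the zinc transporter gene Slc39a12 (5.84) and Phkg1 (3.92) were also among the smallest p. Lower in cortex were Adarb2 (-1.64), Dcaf12l1 (-1.39), Lmcd1 (-1.19) and Unc80 (-1.06), and Trp53 (-1.36) and Fbln5 (-1.20), of which the last pair turned to 1.19 and 0.78 without Co2 by region alone. Gstp1, Nme2, Usp50, Trf and Tgtp2 are uncertain, since 36.0%, 98.9%, 19.1%, 66.0% and 71.7% of their 3' windows occur in other genes.

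**Figure D2:**
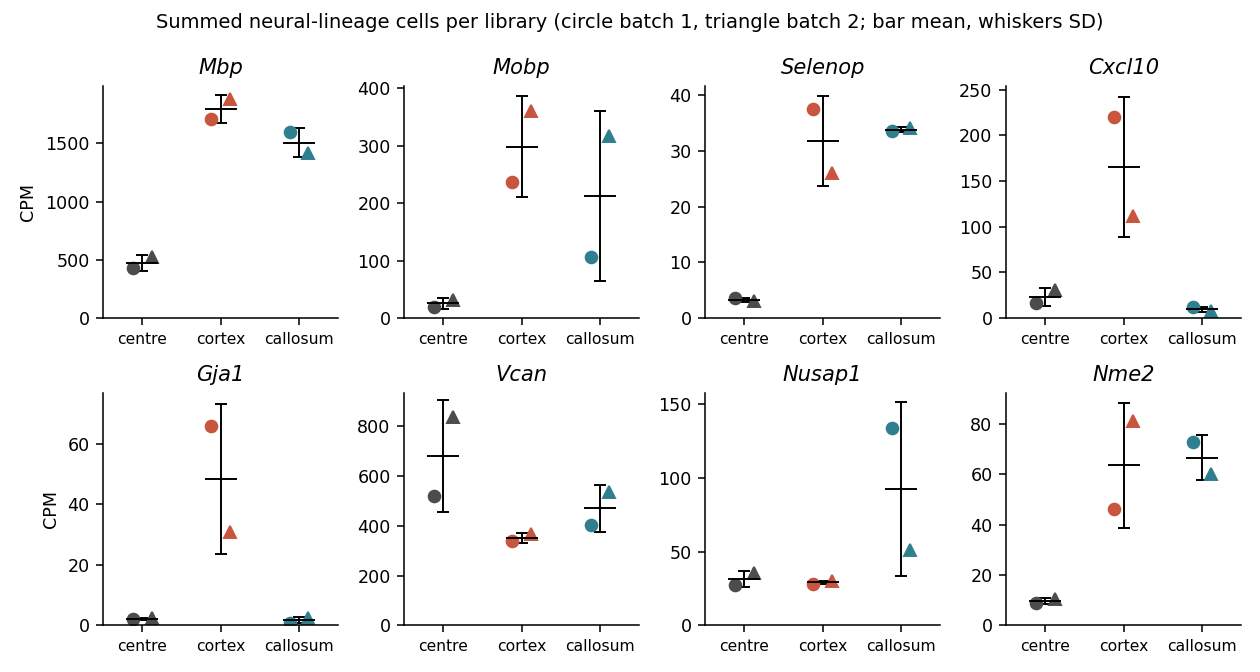
CPM of 8 genes in the neural-lineage cells of each library, with 1 point per library and groups on the horizontal axis. Mbp, Mobp and Selenop are higher in every cortex and corpus callosum library than in either tumour centre library, and Cxcl10 averages 166 CPM in cortex.

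The second comparison, corpus callosum against tumour centre, asks the same of cells in this white matter tract. It shares its tumour centre libraries with the first comparison, so its results are not independent of those above. Myelin genes rose here too, with all 22 measured members higher and a median log2 fold change of 2.62 (camera adjusted p = 8.2e-30, and p = 0.891 with an estimated correlation). The median was 0.81 in batch 1 and 2.92 in batch 2. Mbp averaged 1505 ± 124 CPM in corpus callosum and 474 ± 66.9 in tumour centre, Mobp 212 ± 148 against 26.0 ± 9.23 CPM and Ermn, a cytoskeletal gene of oligodendrocytes, 49.9 ± 53.9 against 4.33 ± 2.36 CPM. Adjusted over the list alone, 9 of 22 passed by region alone and 21 with batch as a term, against 0 and 7 over all genes tested. Mature oligodendrocyte-like cells moved with the list, at 8.12% of neural-lineage cells in corpus callosum and 1.3% in tumour centre.

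Cell division genes rose in corpus callosum relative to tumour centre. Of the genes of the G2 and M phases 51 of 53 were higher, with a median log2 fold change of 0.49 (camera adjusted p = 1.3e-13, and p = 0.978 with an estimated correlation), and of the S phase genes 39 of 42, with a median of 0.30 (adjusted p = 6.1e-05, and p = 0.978 with an estimated correlation). Nusap1, a spindle gene (ENSMUSG00000027306, chromosome 2, 119618298 to 119651244), averaged 92.4 ± 58.7 against 31.5 ± 5.38 CPM, with log2 differences of 2.27 in batch 1 and 0.53 in batch 2. Kif11, a mitotic motor gene, averaged 65.8 ± 8.53 against 34.1 ± 16.3 CPM, Ckap2 73.7 ± 6.8 against 47.3 ± 14.1 CPM, and the cyclin gene Ccne2 18.4 ± 2.4 against 7.63 ± 2.18 CPM. Rrm2 had a log2 fold change of 0.96 and Pcna of 0.98, the last uncertain with 19.6% of its windows in other genes. Counted when adjusted over the list alone, 0 members of either list passed by region alone, and with batch as a term 0 of the G2 and M genes and 4 of the S genes, against 0 over all genes tested. By region alone the G2 and M call was lost without Co1, and the S call without Co1 and without CC2. Those fits set unequal numbers of the batches against each other. With batch as a term both calls held without each library.

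All 24 cholesterol synthesis genes were higher in corpus callosum than in tumour centre, with a median log2 fold change of 0.49 (camera adjusted p = 1.6e-16, and p = 0.891 with an estimated correlation). Msmo1, a sterol oxidase gene, averaged 124 ± 23.5 against 73.6 ± 12.7 CPM, and Idi1 (0.77) and Fdps (0.78) are uncertain because of shared sequence. By edgeR p-values adjusted over the list alone, 0 passed by region alone and 16 with batch as a term, against 0 over all genes tested. Precursor genes fell slightly, with 19 of 20 lower and a median of -0.24 (adjusted p = 0.0018, and p = 0.978 with an estimated correlation), led by C1ql1 (-0.53), Vcan (-0.53) and Sox6 (-0.33). By region alone that call was lost without Co1 and without CC2, but with batch as a term it held without each library. It was lost over Xist-positive cells by region alone (camera adjusted p = 0.0543).

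Interferon response genes fell in corpus callosum, with 27 of 34 lower and a median log2 fold change of -0.64. Camera gave an adjusted p of 5.8e-12, and 0.978 with an estimated correlation. The median was -2.70 in batch 1. By region alone the call was lost without CC1, a fit that leaves corpus callosum with batch 2 alone. This was the only loss among 35 alternatives, and the direction turned in 0 of them. With batch as a term the call held without CC1. Cxcl10 averaged 9.59 ± 3.14 against 23.4 ± 10.1 CPM, and Ifit1 15.5 ± 17.7 against 82.1 ± 79.3 CPM, while Ifi27 had a log2 fold change of -0.45. Adjusted over the list alone, 0 passed by region alone and 15 with batch as a term, against 0 over all genes tested. CC1, with 117 neural-lineage cells, weighed more on other lists. Microglia genes rose, with 14 of 14 higher (adjusted p = 1.4e-04, and p = 0.978 with an estimated correlation), but without CC1, which leaves corpus callosum with batch 2 alone, the test turned to lower (adjusted p = 0.0127, or 0.865 with batch as a term), and the call was lost without Co2 (0.117), over all cells (0.405) and with genes not scaled within batch (0.867). P2ry12, a microglial receptor gene, averaged 21.4 ± 25.4 against 1.62 ± 0.45 CPM, and Selplg (4.51) turned to -2.59 without CC1. The antigen presentation test pointed down (adjusted p = 0.0269, and p = 0.979 with an estimated correlation) although the median of 0.10 and 13 of 22 members pointed up. Without CC1 it pointed up (adjusted p = 5.5e-04, or 0.613 with batch as a term), and also with batch as a term without Co1 (8.4e-13). Without CC1, Psmb8 (-0.61), Psme1 (-0.25) and H2-D1 (-0.44) turned to 0.14, 0.01 and 0.25, and by region alone the call was lost without Co1 (0.143) or Co2 (0.0604), after thinning the libraries (0.0808), at resolution 2 (0.0535) and without shared-sequence genes (0.0793). Genes of mural cells and fibroblasts fell, with 8 of 11 lower (adjusted p = 0.0269, and p = 0.978 with an estimated correlation), led by Mgp (-2.33), Rgs5 (-2.76) and Tagln (-1.72). That call was lost without CC1 (adjusted p = 0.712), under stricter quality control (0.469) and in 5 further choices of cells (0.0562 to 0.104), and without Co2 it pointed up (0.693), where Tagln was 0.42.

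Single genes did not pass for corpus callosum against tumour centre by region alone. EdgeR called 0 of 13311 genes, with 364 at an unadjusted p under 0.05, and DESeq2 called 42 higher and 0 lower. With batch as a term edgeR called 81 higher and 3 lower. These calls are uncertain, since that fit made more false calls on simulated counts than its threshold allows. The total was 48 without CC2, 178 without Cx1, 188 without Cx2, 218 without CC1, 361 without Co2 and 535 without Co1. It fell to 4 over Xist-positive cells, 7 over cells of at least 5000 UMIs, 12 without shared-sequence genes, 39 after thinning and 49 over cells with EGFRvIII. Selenop averaged 33.8 ± 0.5 against 3.29 ± 0.38 CPM (edgeR adjusted p = 0.356 by region, 0.0026 with batch as a term). Gjb6 averaged 1.60 ± 0.88 CPM, at least 11.8-fold over the tumour centre. The myelin genes Opalin (3.17), Ppp1r14a (3.21) and Mobp (3.05) and the membrane protein gene Tmem151a (2.91) were among the largest called with batch as a term, and Tmem151a turned to -0.14 without CC2 by region alone. Rnf213 (-0.97) and Eif2ak2 (-0.91), both induced by interferon, were called lower with batch as a term. The ribosomal protein gene Rps28 (1.04) was also among the smallest p, with 10.47% of its windows in other genes. Nme2, Hist1h2ap, Nutf2, Gstp1 and Usp50 were among the highest or the smallest p, but 98.9%, 92.9%, 41.2%, 36.0% and 19.1% of their windows occur in other genes, and they are uncertain.

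The third comparison, corpus callosum against cortex, sets the peripheral regions side by side. Interferon response and antigen presentation genes had the largest median fold changes among the lists tested, both lower in corpus callosum. All 34 interferon genes had negative log2 fold changes, with a median of -1.70 (camera adjusted p = 2.1e-39, and p = 0.505 with an estimated correlation), and so did all 22 antigen presentation genes, with a median of -1.97 (adjusted p = 2.7e-30, and p = 0.505 with an estimated correlation). Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889) averaged 9.59 ± 3.14 CPM in corpus callosum and 166 ± 76.8 in cortex, a log2 fold change of -4.24 (SE 0.55). B2m, the constant chain of class I molecules, averaged 399 ± 321 against 1414 ± 705 CPM, Zbp1 6.02 ± 5.72 against 58.7 ± 43 CPM and Stat2 12 ± 0.34 against 33.9 ± 15.4 CPM. Nlrc5 (-2.56) and Psme1 (-0.98) followed. Counted when adjusted over the list alone, 1 interferon gene and 0 antigen presentation genes passed by region alone, and 30 and 22 with batch as a term, against 1 and 0 over all genes tested. Both calls held without each library.

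Astrocyte genes fell in corpus callosum relative to cortex, with 21 of 22 lower and a median log2 fold change of -1.05 (camera adjusted p = 1.2e-32, and p = 0.177 with an estimated correlation). Gja1 averaged 1.72 ± 1.04 CPM against 48.3 ± 24.6, the water channel gene Aqp4 1.69 ± 0.4 against 24.6 ± 6.63 CPM and Mlc1 3.06 ± 0.15 against 15 ± 3.2 CPM. By edgeR p-values adjusted over the list alone, 5 passed by region alone and 18 with batch as a term, against 0 and 2 over all genes tested. Astrocyte-like cells were 1.32% of neural-lineage cells in corpus callosum and 4.14% in cortex. Thinned to 2000 UMIs, 20% of 5 such cells in Cx1 and 12.5% of 8 in Cx2 had a UMI of EGFRvIII, against 58.8% of 17 in Co1 and 62.9% of 35 in Co2. Astrocytes without the transgene are therefore not excluded as a source, although the list kept its camera call over cells with EGFRvIII. Cell division genes rose in corpus callosum, with 51 of 53 G2 and M genes higher and a median of 0.58 (adjusted p = 1.3e-25, and p = 0.505 with an estimated correlation). Mki67 averaged 225 ± 48.6 against 111 ± 3.6 CPM, Tpx2, a spindle gene, 78.3 ± 9.06 against 44.0 ± 3.12 CPM, and Nusap1 92.4 ± 58.7 against 29.1 ± 1.15 CPM. Adjusted over the list alone, 0 passed by region alone and 28 with batch as a term, against 0 over all genes tested. S phase genes also rose (36 of 42, camera adjusted p = 2.5e-04, and p = 0.809 with an estimated correlation), led by Ccne2 (0.86), Atad2 (0.87) and Usp1 (0.38). By region alone that test pointed down without Cx1 and without CC2, fits with unequal numbers of the batches. With batch as a term the S call held without each library.

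Other lists passed for corpus callosum against cortex, and each lost its call in some fit without 1 library. Myelin genes fell (21 of 22 lower, median -0.51, camera adjusted p = 4.1e-08, and p = 0.708 with an estimated correlation), led by Ugt8a (-0.47), Mbp (-0.25) and Tspan2 (-0.52). By region alone the test pointed up without CC1 and the call was lost without Cx2. Those fits set unequal numbers of the batches against each other. With batch as a term the myelin call and its direction held without each library. Over all cells the call was lost (camera adjusted p = 0.0509). Glycolysis genes fell (16 of 17, adjusted p = 4.5e-04, and p = 0.505 with an estimated correlation), led by the phosphofructokinase gene Pfkp (-0.92), Aldoc (-0.86) and Pgk1 (-0.40, uncertain with 38.7% shared windows), and the call was lost without Cx2 (adjusted p = 0.364). Immediate early genes rose (21 of 27, adjusted p = 0.0031, and p = 0.69 with an estimated correlation), led by Ier5 (0.68), Klf2 (2.61) and Btg2 (0.94), and were lost without CC2 (adjusted p = 0.951) and Cx2 (0.0938) and at resolution 2 (0.0581), and pointed down over all cells (0.78). Precursor genes rose (15 of 20, adjusted p = 0.0292, and p = 0.809 with an estimated correlation), led by Vcan (0.42), Sox6 (0.22) and Cntn1 (0.34), but pointed down without CC1 (adjusted p = 0.927) and Cx2 (0.783) and were lost over cells with EGFRvIII (0.239), Xist-positive cells (0.336) and in 3 further choices of cells (0.053 to 0.0965).

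Further lists for corpus callosum against cortex held fewer genes. Neural stem genes fell (9 of 16, adjusted p = 0.0239, and p = 0.505 with an estimated correlation), led by Hopx (-1.25), Thrsp (-0.96) and Slc1a3 (-0.48). Mature neuron genes fell (11 of 13, adjusted p = 0.0239, and p = 0.708 with an estimated correlation), led by Uchl1 (-0.46), Snhg11 (-2.33) and Nefm (-0.66). The stem call was lost without CC1 (adjusted p = 0.22), Cx1 (0.23) and CC2 (0.0576), and the neuron call without Cx1, where it pointed up (0.728) and Snhg11 was 0.03, and without CC2 (0.692). Over all cells these calls were lost as well (0.348 and 0.857), as under stricter quality control (0.064 and 0.4), after thinning (0.0735 and 0.0706) and over Xist-positive cells (0.103 and 0.143). Microglia genes rose (14 of 14, adjusted p = 0.0381, and p = 0.809 with an estimated correlation), led by P2ry12 (2.83), Selplg (3.89) and Tmem119 (2.16). Without CC1 they pointed down (adjusted p = 1.1e-06, or 9.2e-05 with batch as a term, with Selplg at -3.27 and Tmem119 at -1.72), and the call was lost without Cx2 (0.932), with batch as a term (0.0858) and after thinning (0.234). Over all cells (0.0814) and with genes not scaled within batch (0.0553) they pointed down. The mural and fibroblast test pointed down (adjusted p = 0.0041, and p = 0.802 with an estimated correlation) with a median of 0.12 and a mean of -1.04, led by Mgp (-3.95), Rgs5 (-4.62) and Pdgfrb (-3.56), and was lost without CC1 (adjusted p = 0.385) and Cx2 (0.857), under stricter quality control (0.399) and at resolution 2 (0.661). Over cells with EGFRvIII it pointed up, and passed with batch as a term (0.0245).

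Single genes did not pass for corpus callosum against cortex by region alone. EdgeR called 0 of 13311 genes, with 186 at an unadjusted p under 0.05, and DESeq2 called 0 higher and 4 lower. With batch as a term edgeR called 1 higher and 7 lower. These calls are uncertain, since that fit made more false calls on simulated counts than its threshold allows. The total was 22 without CC1, 13 without CC2, 61 without Cx1, 28 without Cx2, 383 without Co1 and 361 without Co2. It was 1 over cells of at least 5000 UMIs, 2 over cells with EGFRvIII, 3 over Xist-positive cells, 5 after thinning and 25 without mature oligodendrocyte-like cells. Cxcl10 had an edgeR adjusted p of 0.0335 with batch as a term, as did Rnf213 (log2 fold change -1.45), and Igfbp7, an insulin-like growth factor binding protein gene (-1.80), had 0.033. Gja1, Aqp4, Mlc1, Slc4a4 (-1.81), Pla2g7 (-2.34), Gjb6 (-3.16) and Slc39a12 (-3.92), all expressed in astrocytes, had the smallest p by region alone, with Frmd6 (1.47) and Efcc1 (5.56) higher in corpus callosum.

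**Figure D3:**
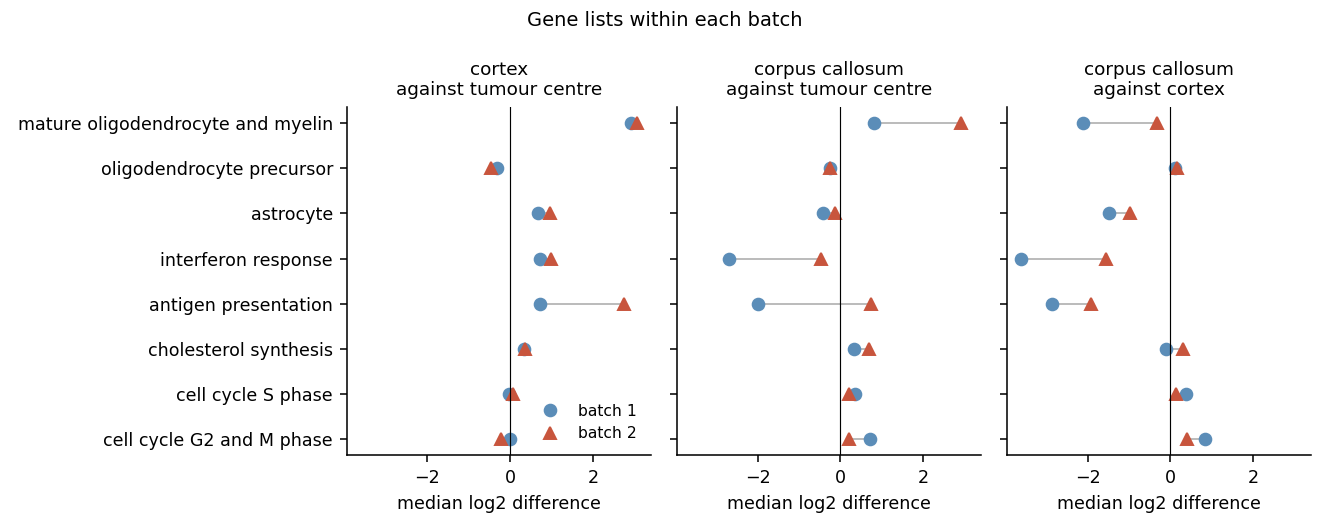
Median log2 difference of 8 gene lists in neural-lineage cells for each comparison, with 1 point per batch. Myelin medians are above 0 in both batches in both comparisons against tumour centre, and interferon medians are -3.62 and -1.55 for corpus callosum against cortex.

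Within the oligodendrocyte precursor-like class alone, myelin genes still rose in cortex against tumour centre. Of 21 measured members 20 were higher, with a median log2 fold change of 1.53 (camera adjusted p = 2.0e-36), and this call held with an estimated correlation (adjusted p = 0.0305) and with fry (0.0302). With batch as a term these tests gave 0.168 and 0.0279. The make-up of the class differed between regions, and a shift toward committed cells within it is not excluded. Its cluster led by Neu4, Enpp6 and Gpr17, genes of committed precursors, was 30.1% of the class in Cx1, 38.1% in CC1 and 12.5% in Co1, and 15.6%, 6.79% and 1.77% in Cx2, CC2 and Co2. These cells were shallow, with medians of 2727 UMIs and 9.04% mitochondrial UMIs, so depth and cell quality are not told apart from such a shift. A deeper cluster led by Tnr, Neu4 and Gpr17 (median 24956.5 UMIs) was 6.93%, 7.72% and 11.2% of the class in Cx2, CC2 and Co2 and 0% in batch 1. Over neural-lineage cells no list held with an estimated correlation in any comparison, by region alone or with batch as a term. Counted when adjusted over the list alone, 12 of the 21 passed by region alone, against 0 over all genes tested. In corpus callosum against tumour centre the class had 19 of 21 myelin genes higher, with a median of 0.88 (adjusted p = 1.2e-13, and p = 0.157 with an estimated correlation), and Mobp averaged 48.4 ± 24.8 against 6.06 ± 0.34 CPM. By edgeR p-values adjusted over the list alone, 2 passed by region alone.

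Interferon genes of the same class separated cortex from corpus callosum, with all 34 lower in corpus callosum and a median of -1.79 (camera adjusted p = 1.5e-24, and p = 0.606 with an estimated correlation). Adjusted over the list alone, 0 passed by region alone and 32 with batch as a term, against 0 and 17 over all genes tested. Gbp2, which encodes an interferon-induced GTPase, averaged 104 ± 135 CPM in cortex, 7.81 ± 9.63 in corpus callosum and 3.72 ± 2.9 in tumour centre. The cluster whose leading genes included the interferon-induced Igtp, Tgtp2 and Ifi47 held 103 of the 231 cells of this class in Cx2 (44.6%), 32 in CC2 and 29 in Co2. EdgeR called 0 of 12926 genes by region alone in each comparison (374, 249 and 146 at an unadjusted p under 0.05 for cortex against tumour centre, corpus callosum against tumour centre and corpus callosum against cortex), and DESeq2 called 42, 34 and 0. With batch as a term edgeR called 281, 133 and 45, and 75, 42 and 11 over Xist-positive cells. The first total moved to 65 without Cx2, 596 without Cx1 and 759 without Co1, and the second to 216 without Cx2, 252 without Cx1, 259 without Co1 and 324 without Co2. The third moved to 6 without Cx2, 25 without CC2, 68 without CC1, 235 without Cx1, 337 without Co2 and 353 without Co1.

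Some genes called higher in both peripheral regions have near-identical copies elsewhere in the genome, so that a short read cannot always be assigned to 1 gene. Genes with at least 50% of their 3' windows in another gene (278 tested) had a median log2 fold change with batch as a term of 0.45 in cortex and 0.55 in corpus callosum against tumour centre, and 0.02 in corpus callosum against cortex. Genes with no shared window (10283) had medians of -0.02, -0.02 and -0.00. Nme2, a nucleoside diphosphate kinase gene, averaged 63.5 ± 24.7 CPM in cortex, 66.6 ± 8.89 in corpus callosum and 9.60 ± 1.21 in tumour centre (SD, n = 2 each). Hist1h2ap, a replication-dependent histone gene, averaged 539 ± 352 CPM in corpus callosum and 41.0 ± 22.6 in tumour centre. Without genes sharing at least 10% of their windows, the totals called with batch as a term were 176, 12 and 8 over neural-lineage cells.

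**Figure D4:**
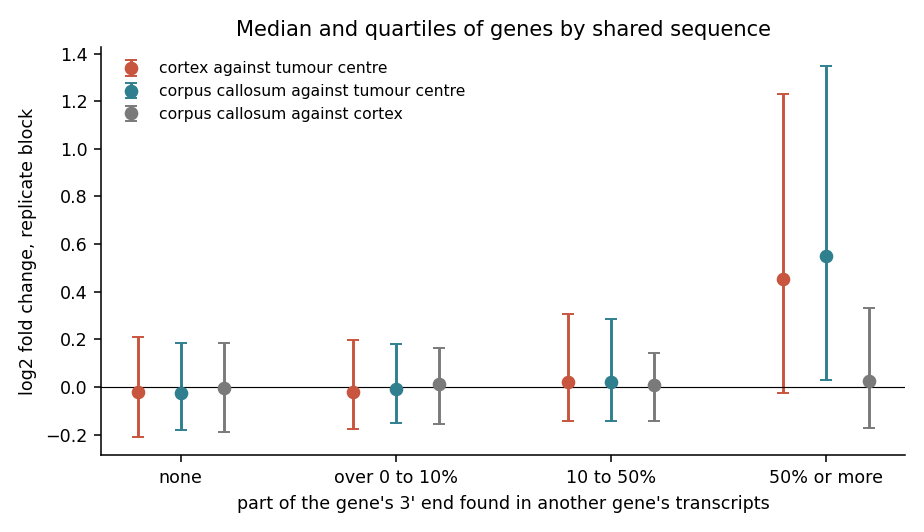
Median log2 fold change with batch as a term (points) and quartiles (lines) of genes grouped by the percent of their 3' windows shared with another gene, for each comparison. Genes with at least 50% shared windows have medians of 0.45 and 0.55 against tumour centre and 0.02 between corpus callosum and cortex.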

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

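The tests of sequence shared between genes, of the myelin list over cells with EGFRvIII, of immune-like cells in batch 2 and of interferon genes in batch 2 were chosen after the result was seen. The following signals were not the subject of the main comparisons between regions, although their cells entered some of the fits. After the sort for tdTomato, 820 of 5917 cells were immune-like. These cells held 57 UMIs of EGFRvIII (5.77 CPM, 45 of 820 cells or 5.49%, median depth 9645.5 UMIs), against 854 CPM and 85.1% of the oligodendrocyte precursor-like cells (median depth 15101). Thinned to 2000 UMIs per cell, the shares were 1.77% and 71.3%, so the immune-like level was read as background. Among cells of at least 5000 UMIs, Y-linked UMIs without any of Xist were found in 397 neural-lineage and 121 immune-like cells of Co1, beside 687 and 180 with Xist alone. Cx1 had 5 such neural-lineage and 11 such immune-like cells, and CC1 had 5 such immune-like cells. In batch 2 the neural-lineage cells with Y-linked UMIs alone numbered 1 in CC2, 1 in Cx2 and 0 in Co2, beside 265, 145 and 1682 with Xist alone.

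Genes with near-identical copies were higher in both peripheral regions, whose comparisons share the tumour centre libraries. Genes with mostly shared 3' ends exceeded the other genes by median log2 fold changes of 0.469 in cortex and 0.569 in corpus callosum, but by 0.0226 between corpus callosum and cortex, so reads shared between copies and handled differently in the tumour centre libraries may be the source. In immune-like cells of batch 1, 24 of 26 such called genes were higher in cortex too, with a median log2 ratio of 1.135 against 1.26 in neural-lineage cells and 0.06 for other genes, which is consistent with a property of the library rather than of the neural-lineage cells. A difference in depth stays open, since thinning the libraries left 0.97 and 0.96 of the medians but leaves expected ratios unchanged by construction. Which step of library making or read assignment differed was not tested, and a difference between regions stays open.

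Myelin genes were higher in both peripheral regions. Over cells with a UMI of EGFRvIII the median log2 fold change of the list with batch as a term was 2.15 instead of 3.14 in cortex against tumour centre, a ratio of 0.686 that leaves open how far mature oligodendrocytes without the transgene contribute. The summed EGFRvIII level of mature oligodendrocyte-like cells was uneven, with 43.1 CPM in Cx1 and 545 in Cx2. Thinned to 2000 UMIs, 10% of 10 such cells in Cx1 and 14.8% of 27 in Cx2 had a UMI of EGFRvIII. Precursor-like cells had 73.7% and 70.2% there. Most mature oligodendrocyte-like cells of cortex thus lacked detected transgene at this depth, while 50% of 38 in CC2 and 56% of 25 in Co2 had it. How far these cells set the list stays open. In batch 1 the list summed to 1071 CPM in immune-like cells of CC1, 920 in Cx1 and 697 in Co1. Precursor-like cells had 4003, 5005 and 2104 CPM there. Free RNA of oligodendrocytes as the whole source in batch 1 is argued against. A part stays open, since immune-like cells were also higher in both peripheral libraries and precursor-like cells may hold myelin RNA of their own. The ratio of immune-like to precursor-like cells was 0.267 in CC1 and 0.184 in Cx1. In batch 2 these ratios were 2.09 (CC2) and 0.734 (Cx2) over only 14 and 16 immune-like cells, too few to decide, so free RNA may contribute there. A difference between regions in the tumour cells themselves stays open and was not tested.

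Interferon response genes were higher in cortex than in corpus callosum. Without the cluster that held 103 of 312 cells of Cx2, the median of the list within precursor-like cells was -1.10 instead of -1.92 with batch as a term, so 1 cluster of 1 library is argued against as the whole cause, although the call for cortex against tumour centre was lost without it. Different shares of pooled animals in batch 1 are argued against as the whole cause, since the median over neural-lineage cells was -1.55 in batch 2 beside -3.62 in batch 1. A part in batch 1 stays open, since animals of 1 sex are not told apart. Both causes together stay open too, since the cluster lay almost wholly in batch 2 and the batch 2 median was taken with its cells. Regional signals from the surrounding tissue stay a hypothesis that was not tested.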

How the results depend on the processing

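The fits over cells with EGFRvIII, Xist-positive cells, cells of at least 5000 UMIs, without the interferon cluster, without shared-sequence genes, and all fits joining batch as a term with another choice were chosen after seeing the data. Values are given for cortex against tumour centre, corpus callosum against tumour centre and corpus callosum against cortex, in that order. By region alone edgeR called 0 genes with RLE size factors, stricter quality control, doublets kept, each clustering, thinned libraries, all cells, each removal of cells or genes and without each library in turn. No cluster was named mature neuron-like, so the planned removal of both mature classes left out mature oligodendrocyte-like cells alone. The 0 does not show stability, since simulated changes of 2-fold and 4-fold were not recovered at this spread either. Among neural-lineage cells the calls were 1, 1 and 0 without quality control, 88, 42 and 4 with DESeq2 and 288, 84 and 8 with batch as a term. Joined with batch as a term, the calls were 64, 49 and 2 over cells with EGFRvIII, 51, 4 and 3 over Xist-positive cells, 92, 7 and 1 over cells of at least 5000 UMIs, 96, 39 and 5 after thinning the libraries, 191, 98 and 25 without mature oligodendrocyte-like cells, 176, 12 and 8 without shared-sequence genes and 358, 75 and 6 without the interferon cluster. Leaving out 1 library at a time gave 0 by region alone and, with batch as a term, 147 to 1010, 48 to 535 and 13 to 383. Within precursor-like cells the calls were 34, 18 and 0 without a filter on low counts, 42, 34 and 0 with DESeq2 and 281, 133 and 45 with batch as a term. With that term they were 221, 103 and 33 over cells with EGFRvIII, 75, 42 and 11 over Xist-positive cells, 194, 80 and 18 over cells of at least 5000 UMIs, 204, 107 and 76 after thinning, 182, 31 and 45 without shared-sequence genes and 215, 159 and 2 without the interferon cluster. Leaving out libraries gave 0 by region alone and 65 to 759, 93 to 324 and 6 to 353 with the term. Fewer cells or genes enter several of these fits, and the causes of the changes were not tested.

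The counts of gene lists, 10, 9 and 13, were 0 with an estimated correlation and 0 with fry in each comparison, while fry with batch as a term called 1 list, the astrocyte genes, for corpus callosum against cortex (adjusted p = 9.4e-04). The first was 5 under stricter quality control. Leaving out libraries gave 11 to 16, 9 to 11 and 9 to 17, and all other alternatives stayed within 1.5 times. With the preset correlation, 2, 2 and 4 lists kept their calls and directions under all 35 alternatives with camera. Some calls lost without 1 library by region alone held in all such removals with batch as a term. These were the precursor, neuron and interferon lists in the first comparison. In the second they included the precursor, S, G2 and M and interferon lists, and in the last the myelin and S lists. Lost or turned most often were, in the first comparison, the committed and stem lists (10 each), in the second the antigen presentation and mural lists (8 each), and in the last the microglia and neuron lists (14 each), the stem (12) and the precursor list (11). The precursor-like share of neural-lineage cells (-7.23, -6.27 and 0.96 points) depended on clustering and filters. For cortex against tumour centre it was -12.8 with doublets kept, -12.7 with genes not scaled within batch, -24.2 without quality control, -17.5 under the stricter one and -19.8 at Leiden resolution 2. For corpus callosum against tumour centre it was -14.9 with genes not scaled within batch, -27.9 without quality control and -17.1 at resolution 2, and for corpus callosum against cortex 13.1 under stricter quality control. The naming of clusters changed as well. A cluster led by Meox1, Stmn3 and Cdo1 was precursor-like in the main clustering. Similar clusters took no name with doublets kept, with genes not scaled within batch and without quality control. Under the stricter filter a cluster of 140 cells, 82.1% with EGFRvIII, was left out as vascular-like. Leaving out libraries gave -8.68 to -5.78, -13.1 to 0.58 and -5.88 to 7.80 points. The share of cells with Mki67 or Top2a for corpus callosum against cortex was 1.68 points at 4000 UMIs and 1.62 without thinning, and without thinning -3.59 for corpus callosum against tumour centre. Leaving out libraries gave -8.59 to 2.85, -1.48 to 9.96 and 2.57 to 11.7 points. The other 18 values of the precursor-like share and 33 of the Mki67 or Top2a share moved by less than 1 SD between libraries. For removals of a library this was fixed by the design and shows no stability. The causes of these changes, naming included, were not tested. A library left alone in its region was assumed to vary like the others.

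Of the log2 fold changes of named genes under the alternatives, 2415 kept direction and side of the threshold, 101 kept direction and passed where the fit by region alone did not (61 with batch as a term, 38 with DESeq2 and 2 without quality control), and 23 changed direction. A gene below the count filter of an alternative has no value there. For cortex against tumour centre, Ier5 was 0.88 over all cells. Leaving out 1 library at a time moved Trp53 from -3.12 to 1.19 and Fbln5 from -2.79 to 0.78, both highest without Co2. For corpus callosum against tumour centre, Psme1 was 0.076 after thinning the libraries. Leaving out libraries moved Psmb8 from -2.92 to 0.135, Psme1 from -0.656 to 0.0135 and H2-D1 from -1.97 to 0.25, and Selplg from 5.63 to -2.59, all turning without CC1. Tagln moved from -10.8 to 0.416, turning without Co2, and Tmem151a from 3.64 to -0.135, turning without CC2. For corpus callosum against cortex, Mbp was 0.087 without quality control, 0.013 over all cells and 0.207 over Xist-positive cells. Over all cells, which include immune-like cells, Nefm was 0.107, Ier5 -0.21, Klf2 -1.61, Btg2 -0.47, P2ry12 -0.84, Selplg -0.80 and Tmem119 -1.70. Leaving out libraries moved Snhg11 from -3.24 to 0.033, turning without Cx1, and Selplg from 11.1 to -3.27 and Tmem119 from 3.54 to -1.72, turning without CC1. The causes were not tested. Depth limits CC1 and Cx1, with 117 and 295 neural-lineage cells and medians of 2504 and 2450 UMIs.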

Other observations

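Several gene groups often followed in glioblastoma did not part the regions over neural-lineage cells. Hypoxia genes had median log2 fold changes of 0.07 for cortex against tumour centre, -0.00 for corpus callosum against tumour centre and -0.09 for corpus callosum against cortex (camera adjusted p = 0.559, 0.955 and 0.374). Genes of the mesenchymal glioma state had medians of 0.13, -0.06 and 0.12 (0.858, 0.575 and 0.239), although within precursor-like cells they rose in cortex against tumour centre (18 of 22 higher, median 0.52, adjusted p = 0.0066, and p = 0.808 with an estimated correlation) and fell in corpus callosum against cortex (16 of 22 lower, median -0.52, adjusted p = 3.0e-04, and p = 0.606 with an estimated correlation). Nuclear genes of oxidative phosphorylation had medians of -0.01, -0.05 and -0.05 (adjusted p = 0.922, 0.295 and 0.239), and neuroblast genes of 0.03, -0.18 and -0.16 (0.9, 0.749 and 0.768).

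Most clusters held cells of 1 batch almost alone. Of the precursor-like clusters, only those led by Neu4, Enpp6 and Gpr17 and by Hist1h2ap and Top2a held many cells of both. Scaling genes within each batch thus did not merge the batches, which limits shares based on clusters. A cluster with leading genes Postn, Foxd3 and Col3a1, which encode matrix and neural crest proteins, held 165 of 2237 cells of Co2, 47 of 444 of CC2 and 8 of 312 of Cx2, but 8 of Co1, 2 of Cx1 and 1 of CC1, and 87.9% of its cells had a UMI of EGFRvIII. A cluster with leading genes Otos, Snhg11 and Ptprn held 143 cells of Co1, 22 of Cx1 and 4 of CC1 and 0 of CC2, Cx2 and Co2. A further precursor-like cluster with high interferon gene levels (11789 CPM of the list) held 133 cells of Co2.

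EGFRvIII levels differed between libraries in precursor-like, astrocyte-like and mature oligodendrocyte-like cells. Precursor-like cells had 1057 CPM in CC1, 1397 in Cx1 and 1435 in Co1, and 797, 793 and 573 in CC2, Cx2 and Co2. Astrocyte-like cells of cortex had 39.1 CPM in Cx1 (2 UMIs in 9 cells, exact interval 4.73 to 141) and 120 in Cx2 (11 UMIs in 15 cells, 59.7 to 214), against 1199 in Co1 (1040 to 1375) and 820 in Co2 (744 to 902). Mature oligodendrocyte-like cells had 665 CPM in CC2, 545 in Cx2 and 376 in Co2, but 201 in CC1 (2 UMIs in 5 cells), 43.1 in Cx1 (5 UMIs in 16 cells) and 78.6 in Co1 (6 UMIs in 10 cells).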
